A study of Mus musculus with 16 samples.

How the data were processed

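RNA was sequenced from red gastrocnemius muscle, the oxidative part of this calf muscle, and from visceral fat of 8 female mice. Of these, 4 carried a knockout of MyD88 restricted to muscle and 4 were Cre-controls. All mice ran on wheels for 5 weeks and then spent 8 days with restricted movement in a small cage. Libraries of both tissues whose subject labels carry the same number were taken to come from the same mouse, which gives 16 libraries in 4 groups of 4. Per the labels' protocols, ribosomal RNA was depleted from total RNA and stranded libraries were sequenced on a NovaSeq instrument.

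The authors deposited raw counts of reads for 55536 Ensembl genes, with 1 column for each library and no scaling. Per the submitters' processing notes, STAR 2.7.0f, featureCounts 1.6.3 and DESeq2 1.22.2 were used with the mouse genome build GRCm38, with no role or order stated. The strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here. All 55536 identifiers were found in the GENCODE M21 annotation of GRCm38, which supplied symbols, gene classes and coordinates. A symbol was shared with another identifier by 233 genes, and 21934 genes had no count in any library. All columns were matched to samples by name. Total counts ranged from 15203806 to 21747345 in muscle and from 13242243 to 19114782 in fat. Reads were counted without molecular identifiers, so intervals computed from counts cover counting error only. No pair of libraries of a group differed by as little as sampling noise in a chi-square comparison of counts, so each was kept as a separate sample.

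From these counts, genotype was tested in each tissue with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts and robust estimation of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no limit on the fold. The difference between the genotype effects in muscle and fat was tested as an interaction over all 16 libraries. Log2 fold changes are knockout over control, and their SE is the absolute log2 fold change divided by the square root of F. Levels are given as CPM, counts scaled to library size with the TMM factors. Levels of the tissue marker genes set side by side in both tissues, of CT010467.1, mt-Rnr2, Upk1a, Myh11, Wfdc2, Hoxa11 and Alb, and mean or summed levels of lists are CPM of total counts without these factors. For Myd88 and the genes past the threshold, a two-sided exact permutation test was also run on log2(CPM + 0.5). With 4 mice against 4 there are 70 assignments, and the smallest p they can give is 0.0286.

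The 45 gene lists, 25 of pathways and 20 of cell type markers, were fixed before the data were examined. They were tested with camera in limma 3.58.1 on voom values, with an inter-gene correlation preset at 0.01, for lists with at least 5 members tested. Of these lists, 36 could be tested in muscle and 38 in fat. Camera with an estimated correlation and the fry test were the alternatives. The rule for genes named in the text was fixed at the same time. It took Myd88, up to 12 genes per direction with the largest change among those past the threshold with a mean of at least 1 CPM and no overlap between the groups, and 6 genes with the smallest p where fewer than 6 passed. It also took up to 4 members with the smallest p from each list that passed, and marker genes of both tissues. Genes with clone names were to be counted and not named. Some genes that the rule took are not reported here. The following were chosen after their values were seen: 9930111J21Rik2, 9930111J21Rik1, Tgtp1 as a gene past the threshold, Tgtp2, Ralgapa2, Tsc22d3, Mt1, Mt2, Gbp9, Gbp10, Coq2, Ppp1r9a, Vldlr, Psmd2, Stt3b, Fam213b, Wfdc21, Gm48880, Ier2 in fat, CT010467.1, mt-Rnr2, Upk1a, Myh11, Wfdc2, Hoxa11, Pax8, Csn2, Wap and Alb.

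Other scalings, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom with and without quality weights, other thresholds, non-robust estimation, 1 fit of all 16 libraries, the mouse as replicate block and leaving out each mouse in turn were the alternatives fixed beforehand. Alternatives without mice 131 and 11, without mice 131 and 139, and those combining the omission of mouse 138 with another tool, correlation or block were chosen after seeing the data, as was the list test of the tissue difference. The mouse number was taken to pair the muscle and fat libraries of an animal. Deviations from the group means of the paired libraries correlated at -0.02 to 0.05 in the controls and at 0.09 to 0.20 in the knockouts, across 17084 genes. Within their group, all 4 knockouts and 1 of the 4 controls, mouse 131, had the highest correlation with the fat library of their own number.

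The procedure was tested on counts simulated from the real means and library sizes, with 200 genes changed. In the muscle simulation, over 13996 genes, edgeR recovered 52.2% of genes changed 1.5-fold and 80.6% of those changed 2-fold. In the fat simulation, over 16140 genes, it recovered 2.99% and 31.3%. Without the library of mouse 138, over 16283 genes, it recovered 32.8% and 64.2%. In the simulated interaction, over 16852 genes, it recovered 4.48% and 31.3%. With no gene changed, edgeR called 0 genes in each of these settings, while DESeq2 called 4 in muscle, 29 in fat, 22 in fat without mouse 138 and 1 for the interaction. Camera with the preset correlation recovered 6 of 6 lists raised 1.5-fold in each tissue and called 0 of 24 lists without a raised member in muscle and 1 of 28 in fat. With an estimated correlation it recovered 6 of 6 in muscle and 5 of 6 in fat and called 0 of the others. Fry recovered 6 of 6 in each and called 1 of the others in each. Genes were drawn independently in these simulations. In the real data the estimated correlation was 0.0314 for atrophy and 0.464 for macrophage genes in muscle. It was 0.0573 for heat shock and 0.927 for adipocyte genes in fat. The simulations therefore cannot show how often camera with the preset correlation errs on the real lists.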

Results

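Gene expression was measured in red gastrocnemius muscle and visceral fat of female mice lacking MyD88 in muscle and of Cre-control mice, with 4 mice per genotype and, by the numbers in the subject labels, both tissues from each mouse. MyD88 is the adaptor through which most Toll-like receptors and the interleukin-1 receptor signal. All mice had run on wheels for 5 weeks and then been confined to a small cage for 8 days, and the series asks how the muscle knockout bears on fat gain during inactivity in females. Muscle libraries held 15203806 to 21747345 counts and fat libraries 13242243 to 19114782. Titin (Ttn) took 21.4 to 23.9% of the counts in muscle.

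The tissues were told apart by their marker genes. Muscle creatine kinase, Ckm, was at 13220 ± 1393 CPM in muscle and 189 ± 128 CPM in fat (SD, n = 8 each). Adiponectin, Adipoq, was at 8.55 ± 7.58 CPM in muscle and 2737 ± 982 CPM in fat (SD, n = 8 each). Skeletal actin (Acta1) and the fast myosin Myh2 were at 18350 ± 1619 and 3769 ± 1185 CPM in muscle, against 363 ± 214 and 67.3 ± 57.8 CPM in fat. The lipid droplet protein gene Plin1 and the leptin gene Lep were at 1436 ± 479 and 784 ± 491 CPM in fat, against 4.57 ± 3.61 and 2.55 ± 2.27 CPM in muscle.

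The targeted gene, Myd88 (ENSMUSG00000032508, chromosome 9, 119335934 to 119341411, GRCm38), was read in every library. In muscle it was at 2.67 ± 0.64 CPM in controls and 1.94 ± 0.20 CPM in knockouts (SD, n = 4 each), and 3 of the 4 knockouts lay below all controls. The log2 fold change was -0.47 (SE 0.20), with an edgeR adjusted p of 0.949 and an exact permutation p of 0.0571. The Myd88 CPM values were 2.17, 2.11, 3.43 and 2.95 in control mice 131, 137, 138 and 11, and 2.13, 2.02, 1.66 and 1.93 in knockout mice 139, 958, 960 and 29. In fat, outside the targeted tissue, Myd88 was at 16.4 ± 1.28 and 15.6 ± 1.26 CPM (SD, n = 4 each; log2 fold change -0.07, SE 0.10; exact permutation p = 0.4). The Myd88 CPM values in fat were 17.7, 14.6, 16.7 and 16.6 in the same controls and 15.6, 17.4, 14.6 and 14.9 in the same knockouts. The counts cover the whole gene and the deleted part is not given in the sources used here, so reads from outside the deleted part, and from other cells of the muscle, remain in them.

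In muscle, the comparison of genotypes asks which transcripts differ in the targeted tissue. Of 14183 genes tested, 2 changed, and both fell in the knockouts: the interferon-inducible GTPase gene Tgtp1 and 9930111J21Rik2, which lie close together on chromosome 11. Tgtp1 (ENSMUSG00000078922, 48985327 to 48994172) had 104 counts over the 4 controls and 1 count over the 4 knockouts, a ratio of 120 per total count (95% interval 21 to 4763; adjusted p = 0.00278). 9930111J21Rik2 (ENSMUSG00000069892, 49015874 to 49051242) had 288 counts in controls and 3 in knockouts, a ratio of 110 (95% interval 37.4 to 538; adjusted p = 5.29e-07). The exact permutation p of each was 0.0286, the smallest possible. Both share sequence with a neighbouring copy, so how reads were divided between copies is uncertain: 79.2% of the 51-base stretches of Tgtp1 also occur in Tgtp2, and 55.9% of those of 9930111J21Rik2 in 9930111J21Rik1. Tgtp2 was at 2.15 ± 1.0 CPM in controls and 2.32 ± 1.27 CPM in knockouts, and 9930111J21Rik1 at 1.72 ± 0.37 and 1.80 ± 0.49 CPM (SD, n = 4 each); neither passed the test, and without mouse 29 their log2 fold changes of 0.08 and 0.05 became -0.22 and -0.01.

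**Figure D1:**
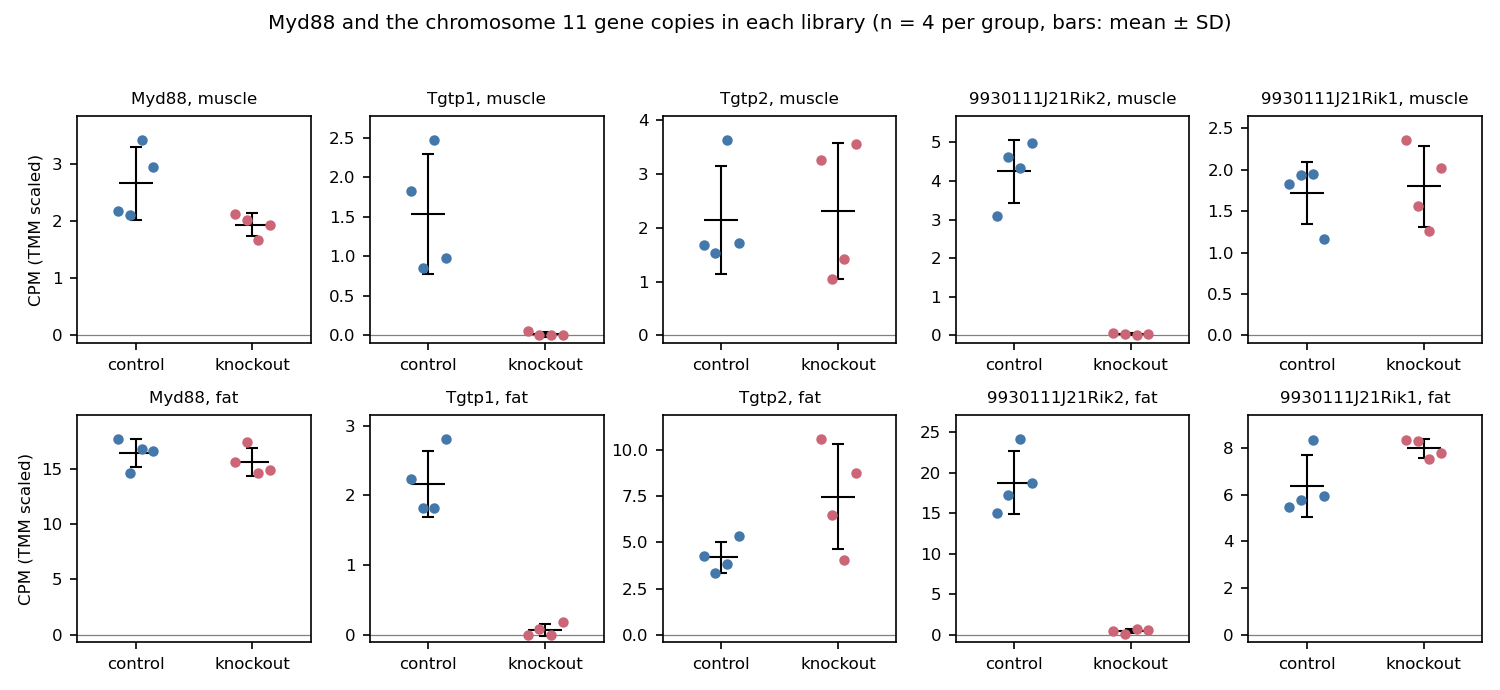
CPM (TMM-scaled, vertical axis) of Myd88 and of the chromosome 11 gene copies in each library of muscle (top) and fat (bottom), in control and knockout mice; points are libraries and bars are mean ± SD, n = 4 per group. Tgtp1 and 9930111J21Rik2 lie near 0 in the knockouts of both tissues, with at most 0.185 CPM of Tgtp1 and 0.648 CPM of 9930111J21Rik2, while Tgtp2 and 9930111J21Rik1 do not.

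The 5 genes with the next smallest p in muscle did not pass the adjusted threshold in edgeR. Ppargc1a, a coactivator of mitochondrial genes, was at 72.2 ± 10.5 CPM in controls and 48.4 ± 2.98 CPM in knockouts (log2 fold change -0.58, SE 0.10, adjusted p = 0.128). The inositol phosphate kinase gene Ip6k3 was at 23.5 ± 1.73 and 15.2 ± 1.92 CPM (log2 fold change -0.63, SE 0.10, adjusted p = 0.103), and the growth factor gene Igf1 at 12.2 ± 1.90 and 18.8 ± 1.28 CPM (log2 fold change 0.63, SE 0.11, adjusted p = 0.159). Ralgapa2, coding for a subunit of a GTPase-activating complex, was at 37.7 ± 5.11 and 24.9 ± 2.53 CPM (adjusted p = 0.159), and the muscle ubiquitin ligase gene Trim63 at 299 ± 46.2 and 206 ± 14.4 CPM (adjusted p = 0.257). For these 5 genes all 4 knockouts lay beyond all 4 controls. This held for 479 of all genes tested in muscle (3.38%, against 2.86% by chance). Genes chosen for a small p tend to separate in this way, so it adds no support. All 5 of these named genes passed with DESeq2 (adjusted p from 0.000287 to 0.00319) and with no filter on low counts (1.28e-06 to 1.05e-05). Ppargc1a passed without mouse 131 (0.0375) and Ralgapa2 without mouse 138 (0.0304). In simulated muscle counts with no gene changed, DESeq2 called 4 genes, and the setting without a filter was not run. Calls with no filter, here and below, therefore carry no known error rate. Over all genes, 715 had an unadjusted p under 0.05 (5.04% of those tested). The number changed was 10 with DESeq2, 80 with no filter on low counts, 4 with quality weights and 1 with at least 1 CPM in at least 4 libraries. It was 10 without mouse 29, 4 without mice 131 and 139, and 1 without mouse 139, when the adjusted p of Tgtp1 was 0.083 although the remaining 3 knockouts held 0 counts of it.

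Among the gene lists in muscle, 9 of 36 passed the test, 8 toward higher and 1 toward lower expression in the knockouts. When the same mice were split in the other possible ways, a median of 11.5 lists passed. Passing this test with the preset correlation therefore does not by itself tie a list to genotype. The list of atrophy and proteolysis genes fell (camera adjusted p = 1.24e-07), with 19 of 22 members lower and a median log2 fold change of -0.175. Its named members were Trim63, Foxo1 (28.3 ± 7.53 against 18.3 ± 2.29 CPM), a transcription factor that drives expression of muscle ubiquitin ligases, and the metallothionein genes Mt1 (13 ± 2.71 against 7.42 ± 1.59 CPM) and Mt2 (3.43 ± 0.28 against 1.94 ± 0.51 CPM; SD, n = 4 each). Of these 22 members, 0 passed over all genes and 5 passed when adjusted over the list alone. With no filter on low counts the 4 named members passed, and with DESeq2 Trim63 and Mt1 did (adjusted p = 0.0030 and 0.0249). With an estimated correlation the list had an adjusted p = 0.0926.

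Lists of immune and stromal cell markers lay higher in knockout muscle. Macrophage markers did so (adjusted p = 1.36e-08), with 13 of 13 members higher and a median log2 fold change of 0.43. The complement gene C1qb was at 2.96 ± 0.85 CPM in controls and 5.10 ± 0.90 CPM in knockouts, and the receptor gene Csf1r at 10.8 ± 1.82 and 15.0 ± 1.45 CPM. The lysozyme gene Lyz2 had a log2 fold change of 0.43 and Adgre1 of 0.48. Mast cell markers were higher for 6 of 6 members (median 0.79, adjusted p = 2.72e-05): the protease genes Tpsb2 (log2 fold change 1.27), Cma1 (1.27), Cpa3 (0.90) and Mcpt4 (0.67), at group means of 0.79 to 2.15 CPM. Antigen presentation genes were higher for 5 of 6 members (median 0.31, adjusted p = 0.00847), among them the class II genes H2-Ab1 (0.46), H2-Eb1 (0.44) and H2-Aa (0.27) and Cd74 (0.35). Extracellular matrix genes were higher for 26 of 26 members (median 0.23, adjusted p = 1.94e-07), with Bgn at 0.33, Mmp14 at 0.32, Lum at 0.28 and Postn at 0.26. Fibroblast and fibro-adipogenic progenitor markers were higher for 12 of 12 (median 0.14, adjusted p = 0.000137), with Pi16 at 0.54, Fbln1 at 0.53 and Dpp4 at 0.29. Over all genes, 0 members of these lists passed in edgeR. Adjusted over the list alone, 3 macrophage, 3 mast cell, 1 antigen presentation, 0 matrix and 0 fibroblast genes passed. With no filter on low counts, C1qb, Csf1r, Lyz2, Tpsb2, Cma1 and Fbln1 passed. With an estimated correlation each of these 5 lists had an adjusted p = 0.611. The antigen presentation list did not pass without mouse 137, 958 or 29 (adjusted p = 0.0613, 0.0718 and 0.0768). The matrix median was 0.078 without mouse 137 and 0.0997 without mouse 29, the mast cell median 0.52 without mouse 137 and 1.20 without mouse 138, and the fibroblast median 0.22 without mouse 131 and 0.21 without mouse 960, all with an adjusted p under 0.05.

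Slow-fibre, respiratory-chain and immediate early genes made up the other lists that lay higher. In the slow-fibre list, 13 of 14 members were higher (median 0.50, adjusted p = 1.04e-05). The slow myosin gene Myh7 was at 1172 ± 128 CPM in controls and 1786 ± 572 CPM in knockouts, with 931 CPM in knockout mouse 29 and 2003 to 2108 CPM in the others. The calcium pump gene Atp2a2 had a log2 fold change of 0.58, and the myosin light chain genes Myl2 and Myl3 of 0.59 and 0.50. The nuclear-encoded oxidative phosphorylation list was higher for 48 of 50 members by a small amount (median 0.07, adjusted p = 0.0034), with Uqcrq at 0.47, Cyc1 at 0.21, Atp5g3 at 0.20 and Atp5g1 at 0.13. Immediate early genes, which answer stimulation or handling within minutes, were higher for 14 of 19 members (median 0.38, adjusted p = 0.0038), with Ier2 at 0.87, Junb at 0.75, Egr2 at 0.62 and Atf3 at 0.52. Of these lists, 0, 0 and 2 members passed when adjusted over the list alone, and 0 over all genes. Their adjusted p with an estimated correlation was 0.611, 0.721 and 0.667. The oxidative phosphorylation list did not pass without mouse 131, 139 or 960 (medians 0.035, 0.020 and 0.038; adjusted p = 0.233, 0.479 and 0.325) or without mice 131 and 11 (0.041; adjusted p = 0.184), its median was -0.02 without mice 131 and 139, and it was 0.12 without mouse 29. The immediate early list did not pass without mouse 29 (median 0.30, adjusted p = 0.408) and had a median of 0.20 without mouse 960 (adjusted p = 0.0449). The slow-fibre list did not pass without mice 131 and 139 (median 0.30, adjusted p = 0.0915), while Myh7, Atp2a2 and Myl2 passed without mouse 29 (adjusted p = 0.00954, 0.00954 and 0.0179), and Ier2 and Junb passed with no filter on low counts.

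The lists closest to the deleted gene did not pass in muscle. The MyD88, Toll-like and interleukin-1 receptor signalling list had an adjusted p of 0.14 (14 of 23 members higher), targets of NF-kB 0.796 (8 of 17 higher), interferon response genes 0.202 (16 of 22 higher) and insulin signalling genes 0.197 (8 of 22 higher). A ribosomal RNA gene, CT010467.1, stood at 27974 and 19833 CPM in the muscle of control mice 131 and 11 and at 16.8 to 35.2 CPM in the other muscle libraries. Without these mice, 2 genes and 14 lists passed.

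**Figure D2:**
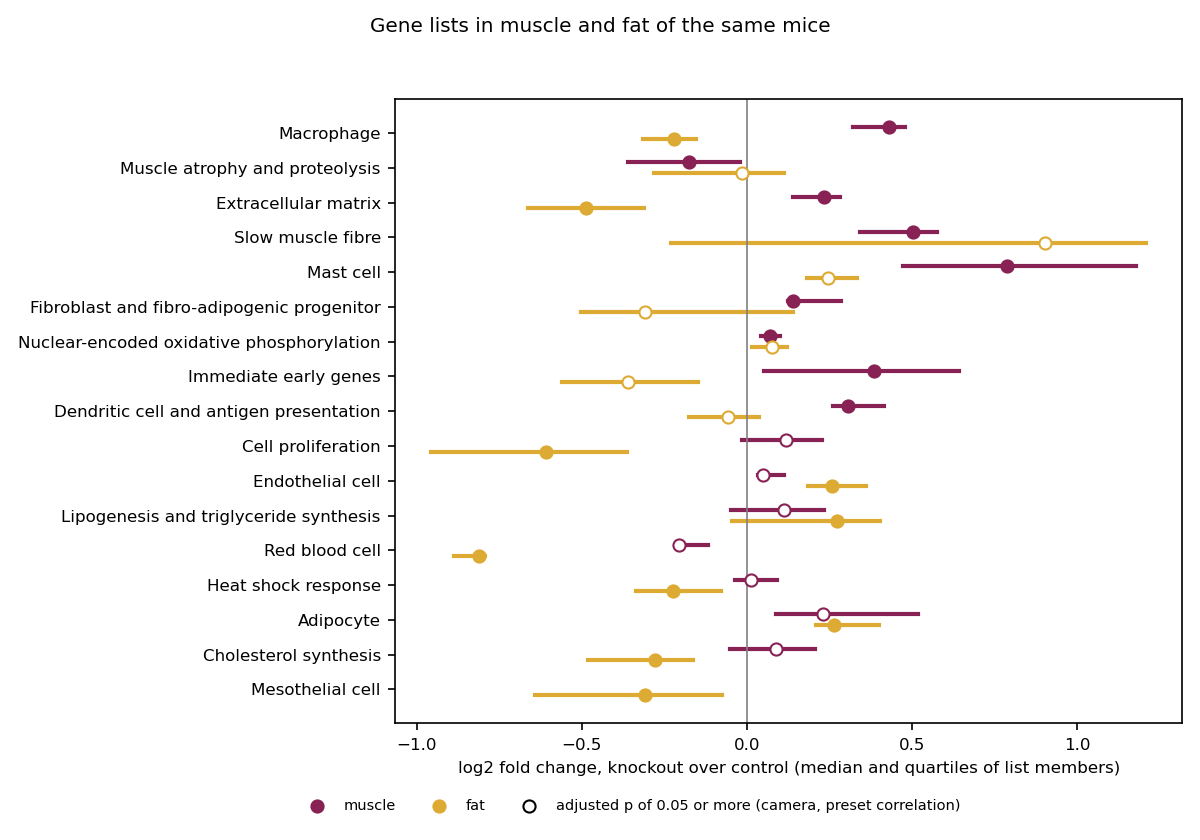
Median log2 fold change (knockout over control, horizontal axis) of each gene list that passed in muscle or fat, with a line from the lower to the upper quartile of its members; filled points have a camera adjusted p under 0.05 with the preset correlation. The extracellular matrix median was 0.23 in muscle and -0.49 in fat, and the macrophage median 0.43 and -0.22.

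In visceral fat, where the knockout was not targeted, the same comparison asks what differs at a distance from the muscle. Of 16323 genes tested, 1 changed: 9930111J21Rik2 fell, from 18.8 ± 3.92 CPM in controls to 0.46 ± 0.27 CPM in knockouts (SD, n = 4 each; log2 fold change -5.30, SE 0.44, adjusted p = 0.026). Tgtp1 was at 2.17 ± 0.47 and 0.065 ± 0.088 CPM, with an adjusted p of 0.187. The other genes with the smallest p did not pass in edgeR either. They were the guanylate-binding protein gene Gbp9 (chromosome 5, 105077630 to 105139539; 28.1 ± 2.36 against 50.7 ± 5.06 CPM; adjusted p = 0.187), the engulfment adaptor gene Gulp1 (37.8 ± 5.12 against 69.5 ± 7.57 CPM; adjusted p = 0.292), the phosphatase gene Dusp4 (27.4 ± 1.06 against 47.3 ± 7.82 CPM), the actin-binding Coro6 (5.80 ± 0.36 against 10.8 ± 1.58 CPM) and Slc26a10 (0.72 ± 0.12 against 1.98 ± 0.27 CPM; adjusted p = 0.294 for these 3). For each, all 4 knockouts lay beyond all 4 controls, as they did for 1038 of all genes tested in fat (6.36%, against 2.86% by chance). As in muscle, this adds no support for genes chosen by their p. With DESeq2 these 5 genes and Tgtp1 passed (adjusted p from 1.54e-08 to 0.00726). Gbp9 lies in a cluster of similar genes, so its counts are uncertain where copies share reads. Tgtp2 was at 4.19 ± 0.86 CPM in controls and 7.49 ± 2.84 CPM in knockouts.

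The fat library of control mouse 138 stood apart from the other 7. The median of its adipocyte list lay at -2.43 on the log2 scale relative to the other controls and that of its smooth muscle list at 3.81, and it held 539 CPM of the bladder epithelium gene Upk1a, against at most 2.40 CPM elsewhere. Without it, 6 of 16579 genes changed. Gbp9 rose (log2 fold change 0.85, adjusted p = 0.0428), and 9930111J21Rik2, Tgtp1, Stt3b, Fam213b and Wfdc21 fell. The neighbouring gene Gbp10 had a log2 fold change of -1.21 in the same libraries (edgeR unadjusted p = 0.00317). How reads were divided between Gbp9 and Gbp10 was not checked. Stt3b, a catalytic subunit of the oligosaccharyltransferase that lies within 10 Mb of Myd88 (chromosome 9, 115242581 to 115310421), fell by 0.90 on the log2 scale (adjusted p = 0.00459), and Fam213b and Wfdc21 had log2 fold changes of -0.78 (adjusted p = 0.027) and -1.04 (adjusted p = 0.0357). Over all 8 libraries, 1305 genes had an unadjusted p under 0.05 (8.00% of those tested), and without mouse 138 there were 2746 (16.6%). The number changed was 72 with DESeq2, 0 with limma voom, 9 with quality weights and 6 in the fit of all 16 libraries, and without mouse 138 it was 348 with DESeq2 and 5 with voom. Leaving out mouse 131, 137, 11, 139, 960 or 29 gave 0 in edgeR, with adjusted p of 9930111J21Rik2 from 0.123 to 0.361 and its log2 fold change from -5.52 to -5.31.

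**Figure D3:**
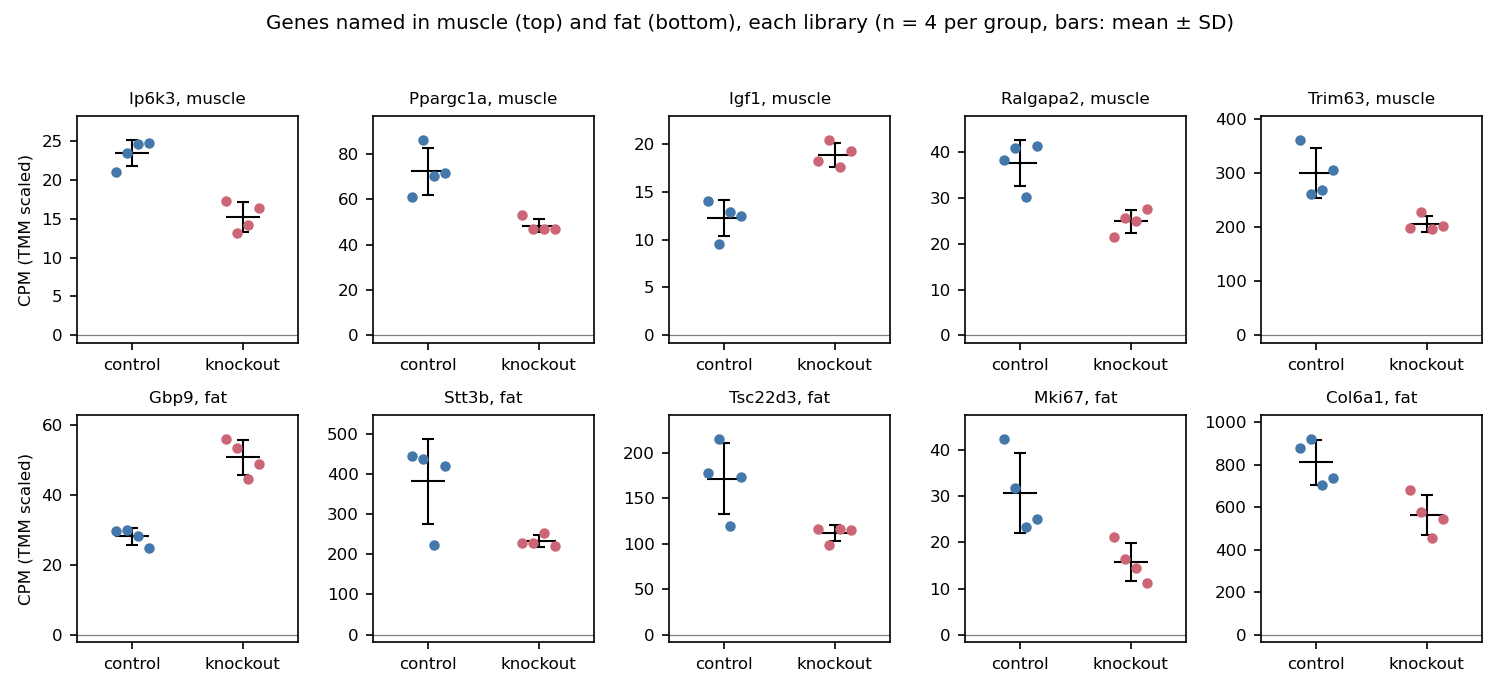
CPM (TMM-scaled, vertical axis) in each library of Ip6k3, Ppargc1a, Igf1, Ralgapa2 and Trim63 in muscle (top) and of Gbp9, Stt3b, Tsc22d3, Mki67 and Col6a1 in fat (bottom); points are libraries and bars are mean ± SD, n = 4 per group. Trim63 averages 299 CPM in control and 206 CPM in knockout muscle, and Gbp9 28.1 CPM in control and 50.7 CPM in knockout fat.

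Genes of cell division and of the matrix were lower in knockout fat. Among the lists, 10 of 38 passed, 3 toward higher and 7 toward lower expression. The other splits of the mice passed a median of 16 lists, so here too passing does not by itself tie a list to genotype. The proliferation list fell (camera adjusted p = 4.06e-13), with 25 of 25 members lower and a median log2 fold change of -0.61. Mki67, a marker of dividing cells, was at 30.7 ± 8.68 CPM in controls and 15.8 ± 4.14 CPM in knockouts, Top2a at 17.9 ± 5.39 and 8.34 ± 2.91 CPM, Cdk1 at 3.60 ± 1.26 and 1.67 ± 0.34 CPM, and Rrm2 at 3.79 ± 1.17 and 1.64 ± 0.43 CPM (SD, n = 4 each). Over all genes 0 members passed and 10 did when adjusted over the list alone, and the adjusted p was 0.531 with an estimated correlation. Among markers of other cells, the summed level of the B cell list was 142, 178, 42.3 and 203 CPM in control mice 131, 137, 138 and 11 and 80.3 to 110 CPM in knockouts (5 of 5 members tested lower without mouse 138, adjusted p = 0.0681), and that of the pancreatic acinar list, too low to be tested, was 8.10 to 20.3 CPM in controls and 4.47 to 7.77 CPM in knockouts. The extracellular matrix list fell (adjusted p = 3.43e-08), with 25 of 27 members lower and a median of -0.49. Col6a1 was at 812 ± 106 and 565 ± 94.7 CPM, Col5a1 at 365 ± 34 and 266 ± 46.2 CPM, Bgn at 161 ± 59.9 and 102 ± 9.28 CPM (log2 fold change -0.66, and -0.37 without mouse 138) and the inhibitor gene Timp1 at 1.85 ± 0.97 and 0.65 ± 0.17 CPM. None of its members passed over all genes or when adjusted over the list alone, and the adjusted p was 0.444 with an estimated correlation. Without mouse 138, 12 of 27 members passed when adjusted over the list alone and 0 over all genes. The adjusted p of the list with an estimated correlation was then 0.949.

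Lists of blood, immune, stress and sterol genes also lay lower in knockout fat. Macrophage markers were lower for 16 of 16 members (median -0.22, adjusted p = 0.0219), with Cd68 at -0.41, Aif1 at -0.40, Trem2 at -0.47 and Ctss at -0.29. Red blood cell genes were lower for 5 of 5 (median -0.81, adjusted p = 0.0179), with Hba-a1 at -0.89, Hba-a2 at -1.0, Hbb-bs at -0.81 and Alas2 at -0.80. Heat shock genes were lower for 12 of 14 (median -0.22, adjusted p = 0.0219), with Dnajb1 at -0.34, Hspa8 at -0.23, and Hspa1b at -0.97 and Hspb8 at -0.26 (-0.27 and -0.14 without mouse 138). Cholesterol synthesis genes were lower for 21 of 24 (median -0.28, adjusted p = 0.0362), with Sqle at -0.65 and Hsd17b7 at -0.46. With an estimated correlation their adjusted p was 0.826 for macrophage, red blood cell and cholesterol genes and 0.759 for heat shock genes. With all mice, 0 members passed over all genes or when adjusted over the list alone. Without mouse 138, 5 of 5 red blood cell genes and 0 macrophage, cholesterol or heat shock genes passed when adjusted over the list alone. The calls of these 4 lists were lost when single mice were left out. Macrophage markers did not pass without mouse 131, 11, 139 or 960 (medians -0.17, -0.10, -0.12 and -0.10; adjusted p = 0.0688, 0.198, 0.375 and 0.196), and red blood cell genes did not without mouse 131 or 137 (-0.53 and -0.64; adjusted p = 0.0799 and 0.0750). Heat shock genes did not pass without mouse 131 or 958 (-0.22 and -0.21; adjusted p = 0.0549 and 0.0857). Cholesterol synthesis genes had a median of 0.02 without mouse 131 (adjusted p = 0.762) and did not pass without mouse 958, 960 or 29 (-0.21, -0.23 and -0.25; adjusted p = 0.190, 0.0760 and 0.0575). The macrophage median was -0.39 without mouse 958 and -0.40 without mouse 29, and the cholesterol median -0.52 without mouse 139. Without mouse 138 these lists, proliferation and matrix kept an adjusted p under 0.05 in the same direction with the preset correlation (macrophage -0.38, cholesterol -0.46, heat shock -0.13) and had an adjusted p = 0.949 with an estimated correlation, and lists of the respiratory chain (median -0.06), the tricarboxylic acid cycle (-0.12) and fatty acid oxidation (-0.09) also passed with the preset correlation, lower in the knockouts.

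The other lists that passed, of fat cells, vessels and the mesothelium, did not pass without mouse 138. Adipocyte markers were higher for 11 of 12 members (median 0.26, adjusted p = 0.0254), with Cfd at 1.02, and Adrb3 at 0.71, Adipoq at 0.55 and Pparg at 0.29 (0.38, 0.22 and 0.10 without mouse 138). Lipogenesis genes were higher for 17 of 24 (median 0.27, adjusted p = 0.00931), with Gpam at 0.54, Fads1 at 0.32 and Srebf1 at 0.40 (0.25 without mouse 138), but Fads2 at -0.88 (0.17 without mouse 138). Endothelial markers were higher for 12 of 12 (median 0.26, adjusted p = 0.00158), with Emcn at 0.42, Vwf at 0.33, and Flt1 at 0.47 and Tek at 0.28 (0.28 and 0.14 without mouse 138). Mesothelial markers were lower for 8 of 10 (median -0.31, adjusted p = 0.0441), with Upk1b at -3.27, Krt19 at -2.35 and Upk3b at -0.65 (0.01, -0.16 and -0.25 without mouse 138), and Msln at -0.62. In each, 0 members passed over all genes or when adjusted over the list alone, and the adjusted p was 0.826 with an estimated correlation. Without mouse 138 the medians were -0.09 for adipocyte, -0.01 for lipogenesis, 0.09 for endothelial and -0.21 for mesothelial genes (adjusted p = 0.851, 0.851, 0.134 and 0.0686). The mesothelial list also did not pass without mouse 131, 11, 139, 960 or 29 (medians -0.32, -0.29, -0.17, -0.06 and -0.29; adjusted p = 0.0688, 0.107, 0.130, 0.366 and 0.0549) or with RLE size factors (adjusted p = 0.0523), and its median was -0.87 without mouse 958. The adipocyte list also did not pass without mouse 29 (median 0.25, adjusted p = 0.0549). The lipogenesis median was 0.46 without mouse 131, 0.17 without mouse 137 and 0.17 without mouse 29. In all 8 fat libraries the MyD88 and Toll-like receptor signalling list had an adjusted p of 0.354 and insulin signalling genes of 0.36.

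**Figure D4:**
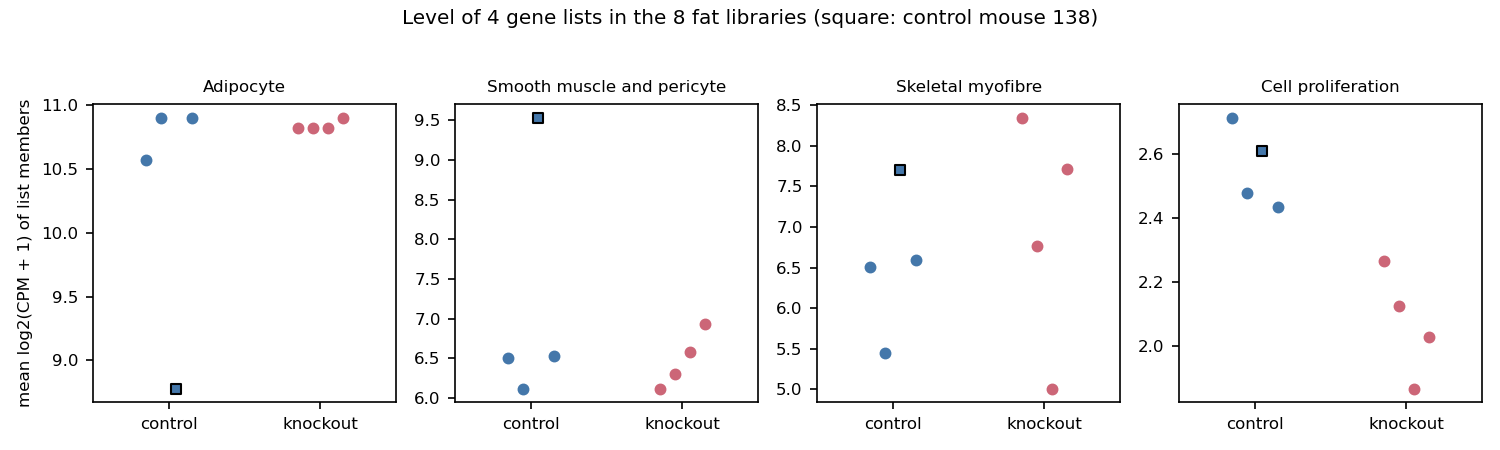
Mean log2(CPM + 1) of the members of the adipocyte, smooth muscle, skeletal myofibre and proliferation lists (vertical axes) in each of the 8 fat libraries by genotype; the square is control mouse 138. In this library the adipocyte level is 8.78, against 10.6 to 10.9 in the other controls.

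The interaction asks whether the genotype effect differs between muscle and fat. Of 17084 genes tested with edgeR, 0 passed, 1229 had an unadjusted p under 0.05 (7.19%), DESeq2 called 11, limma voom 0 and the fit with the mouse as replicate block 0. Without mouse 138, DESeq2 called 118 and the replicate block 7. Across the 13629 genes tested in both tissues, the log2 fold changes in muscle and fat had a Pearson r of 0.02 and a Spearman rho of -0.04, where genes are not independent replicates. The list test of this difference was chosen after seeing the data and does not pair the tissues of a mouse. It passed for 8 lists, led by the extracellular matrix (median of muscle minus fat 0.75, adjusted p = 4.54e-12), macrophage (0.66, adjusted p = 2.52e-05) and proliferation (0.57, adjusted p = 3.19e-05) lists. With an estimated correlation their adjusted p was 0.23, 0.84 and 0.779.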

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

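The comparisons that weigh explanations for the fat library of mouse 138, and the list test of the tissue difference, were chosen after the results were seen. In groups of 4 libraries, a library was singled out when most of the group's range lay between it and its nearest neighbour; the share of the range is given after each value. Chance alone singles out about 1 group in 20. This happened in 4 of 28 groups of library measures (1.4 by chance), 2 of 38 of list levels (1.9 by chance) and 25 of 208 of named genes (10.4 by chance). Genes and lists are not independent of one another, and some genes were chosen after their values were seen. The excess over chance among named genes therefore cannot be weighed.

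The fat library of control mouse 138 accounted for 11 of these. Lower than in the other controls were the level of the adipocyte list (8.78 against 10.6 to 10.9; 0.844), Pparg (124 CPM; 0.846), Srebf1 (145 CPM; 0.894), Stt3b (224 CPM; 0.885) and Fam213b (8.12 CPM; 0.851). Higher were Upk1b (598 CPM against 14.3 to 17.9 CPM; 0.994), Krt19 (221 CPM; 0.98), Fads2 (142 CPM; 0.874), Hspa1b (22.7 CPM; 0.873), Bgn (250 CPM; 0.843) and 9930111J21Rik1 (8.37 CPM; 0.833).

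The following explanations were weighed for this library, which took 59.7% of the variance of the fat libraries on the first principal component. A lower share of adipocytes alone is argued against, because markers of the other cell types would then shift alike, while the smooth muscle list lay at least 4.39 log2 units above the endothelial and macrophage lists (median shifts of 3.81, -0.94 and -0.58); a swap with a knockout mouse is argued against by 24.2 CPM of 9930111J21Rik2, above the other controls. Urinary tract tissue in the sample is a candidate explanation that stays open: all 19 of 19 genes of a urothelial list were highest in this library, where Upk1a was at 539 CPM and the smooth muscle myosin gene Myh11 at 10210 CPM, against 108 to 384 CPM elsewhere; 13 of the 19 reached 1 CPM in another fat library and 7 are also in the lists fixed beforehand. Another epithelium stays open too, since the summed uterus and oviduct list stood at 1244 CPM (8.93 to 18.5 CPM elsewhere) and the mammary list at 1077 CPM (5.52 to 12.5 CPM), of which members shared with the urothelial list gave 1012 and 1025 CPM and 4 of the 9 other members of each list were highest in this library, such as Wfdc2 (163 CPM) and Hoxa11 (27.9 CPM), while Pax8 and the milk protein genes Csn2 and Wap had 0 counts. No biological explanation was tested, since the design gives none for a single control.

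In muscle, mt-Rnr2, a mitochondrial ribosomal RNA that depletion should remove, was at 6108 CPM in knockout mouse 139 against 31180 to 33210 CPM in the other knockouts (0.925), and the ribosomal RNA gene CT010467.1 was at 35.2 CPM in this mouse against 16.8 to 19.6 CPM (0.851). The same mouse had Ppargc1a at 52.8 CPM against 46.8 to 46.9 CPM (0.977) and the only Tgtp1 count among the knockouts (0.0591 CPM against 0; 1). Mitochondrially encoded coding genes took 3.80% of counts in control mouse 137 against 2.94 to 3.02% (0.906). Myh7 was at 931 CPM in knockout mouse 29 against 2003 to 2108 CPM (0.91). Atp5g3 was at 72.5 CPM in control mouse 131 against 109 to 115 CPM (0.867), Tgtp2 at 3.64 CPM in control mouse 138 against 1.54 to 1.72 CPM (0.912) and 9930111J21Rik1 at 1.17 CPM in control mouse 11 against 1.82 to 1.95 CPM (0.834).

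In fat, knockout mouse 958 had higher haemoglobin and haem genes than the other knockouts, with Hbb-bs at 142 CPM against 76.3 to 78.7 CPM (0.963), Hba-a1 at 22.8 CPM against 12.3 to 13.5 CPM (0.885) and Alas2 at 11.3 CPM against 6.02 to 6.86 CPM (0.84), as well as Upk1b at 30.7 CPM against 11.1 to 13.9 CPM (0.854), while Tsc22d3 was at 98.1 CPM against 115 to 116 CPM (0.931). Knockout mouse 960 had mt-Rnr2 at 36980 CPM against 25670 to 27060 CPM (0.877), Mt1 at 60.1 CPM against 36.8 to 39.7 CPM (0.876) and Emcn at 41.9 CPM against 38.2 to 38.6 CPM (0.881). The adipocyte level of knockout mouse 29 was 10.9 against 10.8 in the others (0.971). Control mouse 131 had Top2a at 25.9 CPM against 14.2 to 16.1 CPM (0.837) and Gulp1 at 30.2 CPM against 39.6 to 40.8 CPM (0.881).

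The genotype effect differed between muscle and fat for 8 lists in the list test of the difference, in the fit that does not pair the tissues of a mouse. The median of muscle minus fat was positive for the extracellular matrix (0.753), macrophage (0.661), immediate early (0.637), proliferation (0.57) and fibroblast (0.441) lists, and negative for mitochondrially encoded (-0.431), endothelial (-0.155) and lipogenesis (-0.0983) genes. With an estimated correlation none of the 8 passed, with an adjusted p of 0.23 for the matrix and from 0.779 to 0.84 for the rest. Without mouse 138 the matrix, macrophage, proliferation and fibroblast lists passed and the others did not. In the fit with the mouse as replicate block these 8 lists passed too. So did the cholesterol, heat shock, Schwann cell and antigen presentation lists (camera adjusted p = 0.00601, 0.0189, 0.0233 and 0.0253). With an estimated correlation none passed in that fit (matrix 0.0576). In it, the real grouping gave the smallest p of the 35 splits of the mice for the matrix, proliferation and heat shock lists. Every list tested was ranked in this way, so a first rank can arise by chance, and the ranking kept the fat library of mouse 138. As small a p came from 5 splits for macrophage and for fibroblast genes, 8 for mitochondrially encoded, 9 for immediate early, 19 for endothelial and 22 for lipogenesis genes. It came from 6 for antigen presentation, 10 for cholesterol and 21 for Schwann cell genes.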

How the results depend on the processing

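The alternatives without mice 131 and 11, without mice 131 and 139, and those combining the omission of mouse 138 with another choice were chosen after seeing the data. In muscle, both changed genes kept their direction in each alternative that tested them. The count of 2 was 80 (51 higher, 29 lower) with no filter on low counts, 1 with at least 1 CPM in at least 4 libraries, 10 with DESeq2, 4 with quality weights, 4 without mice 131 and 139, and when each mouse was left out from 1 (without mouse 139) to 10 (without mouse 29). In fat, the count of 1 was 72 (33 higher, 39 lower) with DESeq2, 0 with limma voom, 9 with quality weights, 6 in the fit of all 16 libraries, 348 with DESeq2 without mouse 138, 5 with voom without it, and when each mouse was left out from 0 (without mouse 131, 137, 11, 139, 960 or 29) to 6 (without mouse 138). For the tissue difference, the count of 0 was 11 with DESeq2, 118 with DESeq2 without mouse 138 and 7 with the replicate block without mouse 138, and it stayed at 0 with the replicate block over all mice, which pairs the tissues of each mouse. The 9 lists of muscle and 10 of fat became 0 and 0 with an estimated correlation, 0 and 0 with fry, and ranged from 9 to 12 and from 8 to 14 when each mouse was left out; the muscle lists were 14 without mice 131 and 11, and the fat lists 0 with an estimated correlation without mouse 138. Filters and omitted mice change the genes and samples tested, and for the other settings the cause was not tested. With no filter in muscle, 28344 genes were tested instead of 14183. Named genes had lower adjusted p there at nearly the same fold (Igf1 log2 fold change 0.635 against 0.626). Why was not tested, and this setting was not run on simulated counts.

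Directions turned for 4 genes and 4 lists, none of the genes past the threshold. When each mouse was left out, the log2 fold change in muscle ranged from -0.22 to 0.48 for Tgtp2, negative without mouse 131, 137, 11, 139 or 29, and from -0.0897 to 0.19 for 9930111J21Rik1, negative without mouse 11, 139 or 29; with voom Tgtp2 was at -0.0312. The fat log2 fold change of Fads2 ranged from -1.19 to 0.17 and the fat log2 fold change of Upk1b from -3.73 to 0.0082, both highest without mouse 138. The fat median log2 fold change of list Lipogenesis and triglyceride synthesis ranged from -0.0102 to 0.455 and the fat median log2 fold change of list Adipocyte from -0.0868 to 0.39, both lowest without mouse 138. The fat median log2 fold change of list Cholesterol synthesis ranged from -0.517 (without mouse 139) to 0.0199 (without mouse 131), where the test still leaned lower. The medians without mouse 138 were the same, -0.0102 and -0.0868, with an estimated correlation, which changes the test and not the median. The median of the oxidative phosphorylation list in muscle was -0.0167 without mice 131 and 139. The correlation of fold changes between tissues was 0.000625 (Pearson) over the 12297 genes at 1 CPM or more. Without mouse 138 it was 0.0587 (Pearson) and -0.0537 (Spearman) over 13696 genes. Of the other values of named genes, 665 in muscle and 834 in fat kept their direction and side of the threshold, 29 and 11 newly passed, and 1 and 7 no longer did. Scaling by total counts moved the median of all genes by 0.07 in muscle and -0.05 in fat. Depth limits Tgtp1 and 9930111J21Rik2 in muscle, where knockouts held 1 and 3 counts.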

Other observations

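All tests in this part were chosen after the results were seen, except the glucocorticoid test, whose genes were listed before their values were looked at. A few genes differed the same way in muscle and fat of the same mice. With an unadjusted p under 0.01 in both tissues, 7 genes had the same direction and 2 opposite directions. Besides Tgtp1 and 9930111J21Rik2 they were Ralgapa2 (log2 fold change -0.59 in muscle and -0.80 in fat), the glucocorticoid-induced gene Tsc22d3 (-0.37 and -0.62), the ubiquinone synthesis gene Coq2 (0.37 and 0.46), Slc26a10 (0.68 and 1.45) and Gm48880 (1.03 and 0.64). Of the 35 splits of the mice, 1 gave as many as 7, the real grouping, and the highest other split gave 5, which is the smallest share these splits can give. With Tgtp1 and 9930111J21Rik2 set aside, 2 of the 35 splits gave as many as the remaining 5 (highest other 5), so chance cannot be excluded for the 5 other genes.

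Without mouse 138 there were 12 such genes against 4 with opposite directions. Tgtp1, 9930111J21Rik2, Ralgapa2 and Gm48880 were among them again, while Tsc22d3, Coq2 and Slc26a10 were not. The others were neighbouring guanylate-binding protein genes on chromosome 5 that moved apart, Gbp9 (0.84 in muscle, 0.85 in fat) and Gbp10 (-1.27 and -1.21), the metallothionein genes Mt1 (-0.76 and -0.71) and Mt2 (-0.85 and -1.17), the lipoprotein receptor gene Vldlr (-0.42 and -0.34), the proteasome gene Psmd2 (-0.35 and -0.25), Ppp1r9a (0.44 and 0.27) and Ier2 (1.01 and 0.54). The real grouping was the 1 split of 35 that gave as many, and the highest other split gave 9. With Tgtp1 and 9930111J21Rik2 set aside it was again the 1 split that gave as many as 10 (highest other 9). The margin of 10 against 9 is narrow, and the 10 still hold the neighbouring genes Gbp9 and Gbp10. Chance therefore cannot be excluded for these 10 genes either. A stretch of chromosome 9 carried along with the Myd88 allele and acting on the genes it holds is argued against for the genes alike in both tissues. Of the 7 over all mice and the 12 without mouse 138, 0 and 0 lay within 10 Mb of Myd88. It stays open for Stt3b, which lies there and narrowly missed the count of 7. Its log2 fold change was -0.25 in muscle (edgeR unadjusted p = 0.00544, adjusted p = 0.907). In fat it was -0.71 (edgeR unadjusted p = 0.0109, adjusted p = 0.588). Other inherited differences between the mice, and an effect of the muscle on both tissues, stay open and untested.

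The near loss of Tgtp1 and 9930111J21Rik2 is open to a technical reading, for 9930111J21Rik2 only in part. Loss of MyD88 acting within muscle cells alone is argued against, since the counts were also lower in fat, with control over knockout ratios of 33.6 for Tgtp1 and 40.1 for 9930111J21Rik2. Reads assigned to the near-identical copy instead could account for Tgtp1 in fat. There its counts summed with Tgtp2 had a log2 fold change of 0.25 (95% interval -0.44 to 0.93). In muscle the sum was at -0.68 (-1.71 to 0.35), with 252 counts in controls and 186 in knockouts. Tgtp2 was at 2.15 CPM in control and 2.32 CPM in knockout muscle, and the wide interval cannot tell full from partial reassignment. Reassigned reads cannot be the whole cause for 9930111J21Rik2, whose sum with 9930111J21Rik1 still lay at -1.57 in fat and -1.71 in muscle. A germline variant of these gene copies in the knockout mice is a candidate explanation for both. The lower bounds of the ratio were 12.8 for Tgtp1 and 27.8 for 9930111J21Rik2 over the tissues. The strain background is not given in the sources used here. Neither reading was tested for Gbp9 and Gbp10, which moved apart.

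Tsc22d3, counted over all mice, and Mt1 and Mt2, counted only without mouse 138, were lower and are induced by glucocorticoids, which led to the hypothesis of a weaker glucocorticoid signal in the knockouts. Members of a glucocorticoid list not looked at before had a mean log2 difference of -0.233 in muscle, with 15 of 18 lower (exact permutation p = 0.143), and of 0.0203 in fat, with 11 of 19 lower (exact permutation p = 0.971). The data neither carry nor exclude this hypothesis.

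The counts of changed genes and lists in each tissue did not stand out among the 35 splits of the mice, so chance cannot be excluded for these counts. The number of changed genes ignores how large each change is, so it does not bear on Tgtp1 and 9930111J21Rik2 themselves. Reads of 9930111J21Rik2 numbered 288 in controls against 3 in knockouts in muscle, and 1167 against 29 in fat. Those of Tgtp1 numbered 104 against 1 in muscle and 135 against 4 in fat. In muscle 5 splits gave 2 or more genes (highest other 3) and in fat 2 gave 1 or more (highest other 2). For the interaction the real count was 0, which all 35 splits reach by construction (highest other 1), so it says nothing about chance. For lists, 29 splits gave 9 or more in muscle (highest other 20) and 34 gave 10 or more in fat (highest other 21). The median of the other splits was 11.5 lists in muscle and 16 in fat, above the real counts. Ranked by their own p, the atrophy list in muscle and the proliferation and matrix lists in fat had their smallest p in the real grouping, while 36 and 38 lists were ranked. Of the other muscle lists that passed, 2 splits gave as small a p for macrophage and mast cell genes. The number was 7 for matrix and fibroblast, 8 for slow-fibre and antigen presentation, 12 for immediate early and 16 for oxidative phosphorylation genes. In fat it was 4 for heat shock, 7 for red blood cell, 9 for endothelial and 14 for mesothelial genes. It was 17 for macrophage and cholesterol, 20 for lipogenesis and 31 for adipocyte genes. Without mouse 138, 3 splits gave as small a p for proliferation and 2 for the matrix in fat, a share of 0.0857 and 0.0571. Without mouse 138, 2 splits of the fat libraries gave 6 or more genes, and the highest other gave 104, which points to a structure of these samples unrelated to genotype.

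That split set the fat of mice 11, 29 and 960 against the rest, with 103 of the 104 genes higher in those 3 libraries, among them 14 of 14 genes of a liver list written after the split was seen. The summed level of that list was 344, 681 and 371 CPM in mice 11, 29 and 960, and 96.3, 78.5, 19.9, 65.5 and 51.2 CPM in mice 131, 137, 138, 139 and 958. Albumin, Alb, was at 239, 437 and 218 CPM in the former. The share of fat counts on Ttn, a muscle gene, ranged from 0.0733% to 1.17%.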
